A study of Mus musculus with 16 samples.

How the data were processed

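The values analysed were log2 probe set levels deposited by the authors, made with RMA per the submitters' processing notes, with no version stated. RMA corrects background, normalises between arrays and summarises probes into probe sets. The array library file and genome build are not given in the sources used here. Per the labels' protocols, 150 ng of RNA was amplified and biotin-labelled with a whole-transcript kit and hybridised to GeneChip WT arrays with 1 colour. The table held 41345 probe sets on 16 arrays, with values between 0.54 and 13.39. Its arrays had nearly but not exactly equal quantiles, and no detection calls were used. RMA makes arrays alike in their overall distribution, so a change of most transcripts in one direction would be hidden, and low values are compressed towards a floor.

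Samples were grouped by their labels into epithelium monoculture (2), epithelium co-culture (2), adenoma (4 animals, 6 arrays), fibroblast monoculture (3) and fibroblast co-culture (3). Animals were 8 to 10 weeks old. The 2 arrays of adenoma animals P21 and P34 are technical repeats and were averaged first, which left 14 biological samples of 9 animals. The repeats differed with an SD over probe sets of 0.28 in both animals. Adenoma animals P21 and P23 differed by 0.31 and P34 and P36 by 0.34, against 0.70 between P23 and P36, so these 4 animals may vary less within each pair than independent animals would. The third fibroblast monoculture array carries different animals in 2 of its labels, and its title was followed.

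Probe sets were named through the platform annotation, with symbols updated through gene identifiers (0 changed). Of the probe sets 23521 had 1 gene symbol, 1814 had several and 16010 were unnamed here. Those with 1 symbol covered 22180 genes, each read from its probe set with the highest mean. Genes were tested where the highest of the 5 group means lay above the 30th percentile of probe set means (2.67), which kept 18095 and left out 4085.

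Differences were tested with limma 3.58.1 in R 4.3.3. A mean was fitted for each of the 5 groups with 1 shared spread, followed by empirical Bayes moderation and 2-sided tests with Benjamini-Hochberg adjustment over all genes, called at an adjusted p under 0.05. The total degrees of freedom were 11.7. Comparisons were epithelium co-culture against monoculture, fibroblast co-culture against monoculture, adenoma against each of the epithelial groups, and the difference between both co-culture responses. Pooling assumes that the groups vary alike. Gene lists (30 lists, 505 genes tested) were tested with camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry, which asks whether a list's genes move on balance one way and does not compare them with other genes. At the preset correlation camera treats genes of a list as nearly independent, and most list calls below were lost with an estimated correlation: 1 of 9 held in co-cultured epithelium, 0 of 3 in fibroblasts and 2 of 12 in each adenoma comparison. Fry called 8 lists in co-cultured epithelium, 0 in fibroblasts and 18 in each adenoma comparison. In epithelium these left out cell cycle and epithelial identity genes (adjusted p = 0.136 by fry for each). They took in matrix proteases and inhibitors, which camera had not called.

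Groups, lists, main tests, the rule for named genes and the alternatives were set before the data were examined, except the alternatives and tests named in the text as chosen later. The rule took, per comparison, the 12 largest rises and 12 largest falls past the threshold, and where fewer than 5 passed in a direction the 5 largest with an unadjusted p under 0.01 and groups that did not overlap. It further took up to 4 members of each list with the smallest p, the 6 largest interaction differences each way, and always Apc, Lgr5, Acta2, Epcam, Vim and Col1a1. Eif2s3y, Xist and the genes described only in the closing section were chosen otherwise, as stated there, after their values were seen.

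Mono- and co-cultures come from the same animals, per the labels. Deviations from group means correlated across genes within an animal at 0.33 for epithelium and at 0.62, 0.51 and 0.79 for the 3 fibroblast animals. The animal was left out of the main model and entered as a replicate block in an alternative. The other alternatives were no filter and a 50th percentile filter on dim genes, a fit on the compared groups only, cyclic loess between the arrays compared, a trended robust variance prior, the mean of all probe sets of a gene, a 2-fold minimum, an adjusted p under 0.1, single adenoma arrays, all adenoma arrays with the animal as a random block, and leaving out each sample. Random-block list tests used camera on the moderated statistics.

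The functions were tested on simulated data with the real gene means, a single pooled SD per gene for all groups and 200 genes changed, over 18095 genes. Its noise was independent between samples and between genes. The assumption of equal spread, the pairing of cultures and correlated genes were therefore not tested. For epithelium co-culture 42% of 2-fold and 87% of 4-fold changes were recovered, with 7 false among 136 calls. For fibroblast co-culture 60% and 95% were recovered, with 6 false among 161 calls. For adenoma against monoculture 60% and 90% were recovered, with 14 false among 164 calls. Figures were drawn with matplotlib in Python.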

Results

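Gene expression was measured on 16 microarrays of cells from the small intestine of the mouse. Wild-type crypt epithelium grown as 3-dimensional organoids was profiled alone (monoculture, n = 2 animals) and together with intestinal myofibroblasts (co-culture, n = 2, from the same 2 animals). The myofibroblasts, contractile matrix-producing cells of the intestinal stroma, were profiled alone (n = 3) and with organoids (n = 3, from the same 3 animals). In co-culture the cell types were kept apart by a membrane insert with 0.4 µm pores for 24 h, so that only soluble material was meant to pass. A further group held adenoma cells from 4 animals carrying the Apc 1638N mutation in 1 of the gene copies, on 6 arrays. Apc is the negative regulator of Wnt signalling whose loss starts intestinal tumours. Values are log2 levels, differences are log2 differences ± SE from limma with group sizes as above, and 18095 genes were tested. Array medians lay between 3.48 and 3.58, and the number of arrays limits the precision.

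The 18 epithelial identity genes averaged 10.23 ± 0.06 (SD, n = 2) in monocultured epithelium and 3.58 ± 0.19 (SD, n = 3) in monocultured fibroblasts. The 18 fibroblast identity genes averaged 3.81 ± 0.06 (SD, n = 2) and 9.78 ± 0.13 (SD, n = 3). The fibroblast samples also carried markers of another cell type: the 13 tested markers of immune cells averaged 8.19 ± 0.17 (SD, n = 3) in fibroblast monoculture, against 3.87 ± 0.18 (SD, n = 2) in epithelial monoculture. All 16 arrays are labelled male, yet 4 of the 14 biological samples had Xist, the transcript of the inactive X chromosome, between 7.57 and 8.29 and the Y-linked Eif2s3y between 2.53 and 3.20. These were both cultures of epithelial animal P28 and both cultures of fibroblast animal Pl_III. The other 10 samples had Xist at most at 2.81 and Eif2s3y at least at 7.37.

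The first comparison asked how epithelium changes when myofibroblasts share its medium. In co-cultured organoids 490 genes rose and 239 fell. Krt4, a keratin of stratified epithelium, rose by 3.47 ± 0.45 (adjusted p = 0.00203), from a mean of 6.20 to 9.67. The serine protease inhibitor Serpinb9b rose by 3.55 ± 0.76, but its 2nd probe set differed by 1.10. Krt80 rose by 3.16 ± 0.32, the surface antigens Psca by 3.05 ± 0.71 and Msln by 2.86 ± 0.38, and Mal by 2.89 ± 0.54. Ccnd1, the cyclin of the G1 phase, rose by 3.27 ± 0.31 (adjusted p = 4.1e-04), and Nid1, a basement membrane protein, by 3.37 ± 0.31. Ly6g, Dynap, Slc25a48 and S100a7a completed the 12 largest rises, at 2.98 to 3.31. The largest fall was that of Cyp1a1, a cytochrome P450 induced through the aryl hydrocarbon receptor, which fell by 2.65 ± 0.32 (adjusted p = 0.00161). Cyp2d13, Cyp2c38 and Cyp2j5 fell by 2.22, 2.14 and 2.01, the glucuronosyltransferases Ugt2b36 and Ugt2b5 by 2.30 and 1.91, and the carboxylesterases Ces1d and Ces1g by 2.04 and 1.97. The transporters Slc5a11 and Slc9a3 fell by 1.99 and 1.93, the alcohol dehydrogenase Adh4 by 1.94 and the chemokine Ccl25 by 1.88.

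The list of fetal and repair epithelium genes, expressed in fetal gut and in regenerating crypts, had 7 of 13 members that rose and 0 that fell (8 and 0 adjusted over the list alone). Its median difference was 1.28 (camera, adjusted p = 3.8e-08; adjusted p = 0.00879 with an estimated correlation). Anxa1 rose by 1.97 ± 0.16, Anxa3 by 2.40 ± 0.36 and the alarmin Il33 by 2.24 ± 0.34. Among 14 targets of YAP, a transcriptional coactivator of the Hippo pathway, 5 rose and 0 fell (8 and 1 adjusted over the list alone), with a median of 1.07 (adjusted p = 1.3e-06; adjusted p = 0.185 with an estimated correlation). Ajuba rose by 2.66 ± 0.40, Ptpn14 by 2.22 ± 0.21, Amotl1 by 2.20 ± 0.28 and Ccn1 by 1.73 ± 0.35.

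All 24 cell cycle genes had a positive difference, with a median of 1.31, and 4 of them rose past the threshold (5 adjusted over the list alone; camera, adjusted p = 3.7e-09; adjusted p = 0.458 with an estimated correlation). The 4 were Mcm3 (2.40 ± 0.53), Rrm2 (2.18 ± 0.52), Mcm2 (2.00 ± 0.48) and Ccne1 (1.28 ± 0.28), and for Rrm2 a 2nd probe set differed by 0.50. With the animal as a replicate block, 20 of the 24 rose. Immediate early genes had 2 of 16 members that rose, Nr4a1 by 1.99 ± 0.41 and Fos by 1.43 ± 0.32 (4 adjusted over the list alone; camera, adjusted p = 1.4e-04; adjusted p = 0.157 with an estimated correlation). Of 16 ErbB ligands and feedback genes only Phlda1 passed, with a rise of 1.44 ± 0.21 (2 adjusted over the list alone), and the list had an adjusted p of 0.00904 (adjusted p = 0.0745 with an estimated correlation). No single gene of the 18 of epithelial identity passed over all genes (1 adjusted over the list alone). Their median was 0.35 (camera, adjusted p = 0.0115; adjusted p = 0.382 with an estimated correlation).

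3 lists were called lower. Of 22 genes of absorptive enterocytes, 2 fell (7 adjusted over the list alone), the metalloprotease subunit Mep1a by 1.25 ± 0.25 and the apolipoprotein Apoc3 by 0.87 ± 0.16, and the median was -0.48 (camera, adjusted p = 3.9e-04; adjusted p = 0.0745 with an estimated correlation). Fatty acid oxidation and PPAR genes had 3 of 18 that fell (5 adjusted over the list alone; camera, adjusted p = 5.3e-04; adjusted p = 0.108 with an estimated correlation). They were the coactivator Ppargc1a (-1.70 ± 0.39), the thiolase Acaa1b (-1.53 ± 0.34) and the receptor Ppara (-0.90 ± 0.21). None of 14 tuft cell genes passed singly, over all genes or over the list alone, while their median was -0.37 (camera, adjusted p = 0.00611; adjusted p = 0.0745 with an estimated correlation). The other 21 of the 30 lists were not called by camera. Members that rose in these included the plasminogen activator Plat (2.48 ± 0.25), the urokinase receptor Plaur (1.94 ± 0.25), Myc (1.80 ± 0.35), Cd44 (1.70 ± 0.38), Cdk6 (2.19 ± 0.28) and the hexokinase Hk2 (1.76 ± 0.21). Matrix proteases and inhibitors, with 3 rises among 19, were called higher by fry (adjusted p = 0.00724) but not by camera (adjusted p = 0.0604). The stem cell gene Lgr5 (-0.19 ± 0.29, adjusted p = 0.837), Apc (0.10 ± 0.31), Epcam (0.06 ± 0.42), Acta2 (-0.14 ± 0.40), Vim (-0.28 ± 0.19) and Col1a1 (0.05 ± 0.19) did not pass.

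These counts came from limma on all 5 groups, which share one estimate of the spread. Fitted on the 4 epithelial arrays alone, 0 genes passed, with 3659 at an unadjusted p under 0.05, and with the animal as a replicate block 1922 genes passed, 699 of them shared with the 729. Leaving out 1 of the 4 samples in turn left 202 to 389 genes, and leaving out animal P28, together with fibroblast animal Pl_III, left 68. Of the genes named above, the call of Ppara was lost in 7 of 12 alternatives, and those of Serpinb9b, Psca, S100a7a, Ces1g, Ccn1, Rrm2, Mcm2, Nr4a1, Fos, Mep1a, Ppargc1a and Cd44 in 6 of 12 each.

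**Figure D1:**
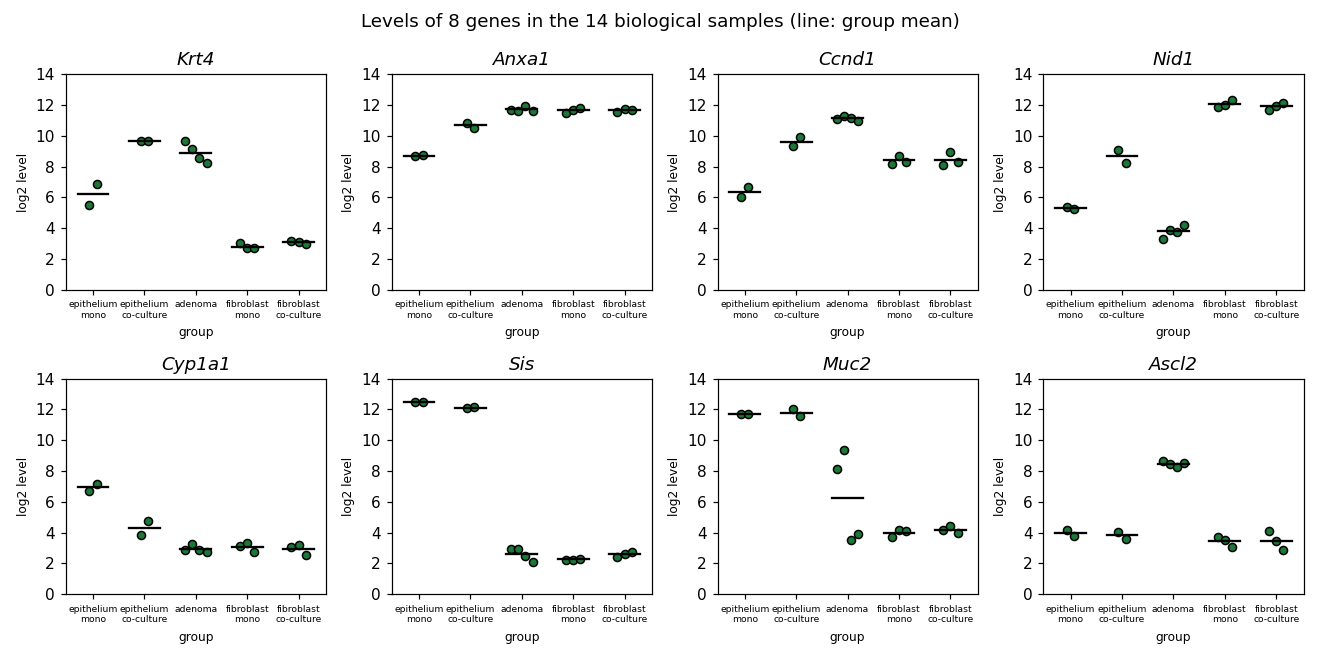
Log2 level (vertical axis, 0 to 14) of 8 genes in the 14 biological samples by group, 1 point per sample and a line at each group mean. Krt4, Anxa1, Ccnd1 and Nid1 were higher and Cyp1a1 lower in co-cultured than in monocultured epithelium, Sis fell from a mean of 12.47 to 2.61 in adenoma, and Muc2 in the 4 adenoma animals lay at 8.13, 9.38, 3.53 and 3.92.

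The second comparison asked how myofibroblasts respond to organoids. In co-cultured fibroblasts 0 genes rose and 1 fell. Mfap4, a microfibril-associated matrix protein, fell by 1.06 ± 0.12 (adjusted p = 0.0401), from a mean of 4.40 to 3.35. At an unadjusted p under 0.05 there were 513 genes, where chance gives 905. This fit ignores that both cultures came from the same animals, so differences between animals widen its SEs. The low count is therefore no evidence that small changes, or changes of few genes, are absent. In the simulated data this fit recovered 60% of 2-fold and 95% of 4-fold changes in fibroblast co-culture. The single call thus argues against many 4-fold changes, as far as the equal spread and independent noise of the simulation hold. The largest differences that did not pass were Hoxd9 (1.29 ± 0.21), the fatty acid carrier Fabp4 (1.02 ± 0.25), Slfn3 (0.96 ± 0.29), Gm15128 (0.94 ± 0.18) and the BMP target Id3 (0.93 ± 0.23) on the higher side. On the lower side they were Elfn1 (-0.97 ± 0.20), Plek2 (-0.82 ± 0.16), Gm6194 (-0.80 ± 0.24), Mir5100 (-0.77 ± 0.22) and Sspn (-0.77 ± 0.20). The myofibroblast actin Acta2 (-0.03 ± 0.33), Col1a1 (-0.14 ± 0.16), Vim (-0.05 ± 0.16), Apc (-0.06 ± 0.25), Lgr5 (-0.08 ± 0.23) and Epcam (0.25 ± 0.35) did not pass either. Mfap4 was not called with the animal as a replicate block, where 0 genes passed and 1352, more than the 905 of chance, had an unadjusted p under 0.05. It was also lost when only the 6 fibroblast samples were fitted (404 genes at an unadjusted p under 0.05) and in 5 of the 6 fits that left out 1 sample.

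3 lists were called in fibroblasts, with 0 members of each passing singly. Interferon response genes had positive differences in 21 of 22 members and a median of 0.62 (camera, adjusted p = 3.0e-09; adjusted p = 0.987 with an estimated correlation). Ifit1 differed by 1.82 ± 0.79, Mx2 by 1.20 ± 0.51, Irf7 by 1.00 ± 0.51 and Irf9 by 0.85 ± 0.31. The median of the list was 1.36 in animal Pl_I, 0.36 in Pl_II and 0.24 in Pl_III. Markers of immune cells had medians of 0.36, 0.01 and 0.04 in the same animals. Without the co-culture sample of Pl_I the call was lost (median 0.02, adjusted p = 0.798). With both samples of Pl_I left out, chosen after the data were seen, it held (median 0.23, adjusted p = 0.00119). Hypoxia and glycolysis genes had a median of 0.21 (adjusted p = 0.0151; adjusted p = 0.987 with an estimated correlation), and p53 targets a median of -0.22 (adjusted p = 0.0217; adjusted p = 0.987 with an estimated correlation). Both calls were lost without animal Pl_I (adjusted p = 0.240 and 0.555). Adjusted over the list alone, 0 members of the 3 lists passed. With the animal as a replicate block, 8 lists were called instead of 3.

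Whether the cell types answered co-culture differently was tested as an interaction. For 200 genes the response of epithelium differed from that of fibroblasts, 151 with a more positive difference in epithelium and 49 with a more negative one. The largest positive differences of response were Krt80 (3.64 ± 0.41), Nid1 (3.52 ± 0.40), the annexin Anxa8 (3.30 ± 0.45), Ccnd1 (3.24 ± 0.40), Krt4 (3.18 ± 0.58) and Pbp2 (3.05 ± 0.51). The largest negative ones were Cyp2c38 (-2.80 ± 0.43), Cyp1a1 (-2.52 ± 0.41), Ugt2b36 (-2.34 ± 0.37), Cyp2j9 (-2.26 ± 0.24), Slc5a11 (-2.19 ± 0.37) and Ces3a (-2.11 ± 0.24). None of these genes passed in fibroblasts alone. A gene that fibroblasts hardly express cannot fall there, so the test does not tell a different answer from absent expression. With the animal as a replicate block 862 genes passed, 191 of them shared with the 200. Leaving out 1 sample in turn left 56 to 164 genes, and leaving out animals P28 and Pl_III left 5. The call of Krt4 was lost in 9 of 18 alternatives.

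The third comparison set adenoma cells against wild-type epithelium alone. Here 4069 genes were higher and 3353 lower in adenoma, 41.0% of those tested. The excess of higher genes turned round after cyclic loess, with 3581 higher and 3751 lower. All 22 absorptive enterocyte genes fell (22 adjusted over the list alone), with a median of -6.58 (camera, adjusted p = 3.1e-20; adjusted p = 5.0e-04 with an estimated correlation). Sis, the brush border sucrase-isomaltase, fell by 9.86 ± 0.21 (adjusted p = 2.6e-11), and the fatty acid carriers Fabp1 and Fabp2 fell by 8.89 ± 0.20 and 7.98 ± 0.37. The apolipoprotein Apoa4 fell by 8.36 ± 0.22 and the retinol carrier Rbp2 by 8.69 ± 0.24. The other largest falls were 2010106E10Rik, Enpep, Cyp2c29, Btnl1, Arg2, Clec2h and Clca4b, by 7.99 to 9.03. In adenoma Sis, Fabp1, 2010106E10Rik, Cyp2c29 and Btnl1 had means under the dim level of 2.67, so their differences are lower bounds. A 2nd probe set of Cyp2c29 at a mean of 2.27 differed by only -0.52. Fatty acid oxidation and PPAR genes fell in 16 of 18 cases (16 adjusted over the list alone; median -1.85, adjusted p = 3.1e-09; adjusted p = 0.0171 with an estimated correlation), Ppara by 5.40 ± 0.19 and Cyp4b1 by 4.23 ± 0.24.

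Among the 12 largest rises in adenoma, the membrane repair protein Myof rose by 7.07 ± 0.32 (adjusted p = 1.3e-08), the membrane-actin linker Msn by 6.52 ± 0.24, the GABA receptor subunit Gabrp by 6.61 ± 0.38 and fibronectin, Fn1, by 6.19 ± 0.42. Thbs1 rose by 5.67 ± 0.50, Efemp1 by 6.26 ± 0.63, Timp2 by 5.19 ± 0.16 and the cytochrome P450 Cyp1b1 by 5.39 ± 0.41. Crip2, Tbc1d19, Cybrd1 and Plekhs1 rose by 5.12 to 5.66, for Tbc1d19 from a mean under the dim level and so as a lower bound. For Msn a 2nd probe set, at a mean of 1.83, differed by -0.03. Col1a1 differed by 0.11 ± 0.17 and Vim by -0.31 ± 0.17, neither passing, and the 18 fibroblast identity genes had a median of -0.15. Acta2 rose by 1.19 ± 0.35 (adjusted p = 0.0161), a call lost in 4 of 18 alternatives (0.70 to 1.69).

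Of 23 Wnt targets 15 rose and 3 fell (15 and 3 adjusted over the list alone), with a median of 1.92 (camera, adjusted p = 6.0e-04; adjusted p = 0.301 with an estimated correlation). Ascl2, a transcription factor of crypt stem cells, rose by 4.51 ± 0.29, Ccnd1 by 4.78 ± 0.27, Cd44 by 3.78 ± 0.33 and Sox9 by 3.51 ± 0.28. The 16 genes of Lgr5 stem cells had 9 rises and 1 fall (9 and 1 adjusted over the list alone; adjusted p = 0.0104; adjusted p = 0.306 with an estimated correlation). The adenoma animals lay apart here, with Wnt targets averaging 7.37, 7.35, 6.34 and 6.30 in P21, P23, P34 and P36 and Lgr5 stem cell genes 7.61, 7.57, 6.60 and 6.71. Without P21 and P23, chosen after the data were seen, the Wnt list was still called (median 0.92, adjusted p = 0.00395) and the Lgr5 stem cell list was not (adjusted p = 0.0657). The probe sets of Lgr5 disagreed, with 0.55 ± 0.25 (adjusted p = 0.0980) for the brighter and a difference of 3.35 for the other. Apc differed by 0.27 ± 0.27 (adjusted p = 0.472), and where its probes lie relative to the 1638N change is not given in the sources used here, so this value checks nothing about the genotype. Epcam differed by -0.69 ± 0.37 (adjusted p = 0.163).

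Of 24 cell cycle genes 23 rose (23 adjusted over the list alone; median 3.23, adjusted p = 3.4e-10; adjusted p = 0.348 with an estimated correlation), Mcm3 by 4.81 ± 0.46 and Mcm2 by 4.18 ± 0.42. YAP targets had 11 rises and 1 fall among 14 (11 and 1 adjusted over the list alone; adjusted p = 1.3e-04; adjusted p = 0.301 with an estimated correlation), with Ptpn14 at 4.91 ± 0.18 and Ccn1 at 4.19 ± 0.31. Fetal and repair genes had 8 rises among 13 (8 adjusted over the list alone; adjusted p = 0.00233; adjusted p = 0.0683 with an estimated correlation), with Msln at 3.82 ± 0.33 and Anxa1 at 2.99 ± 0.14. Targets of p53 had 7 rises and 1 fall among 14 (7 and 1 adjusted over the list alone; adjusted p = 0.0385; adjusted p = 0.583 with an estimated correlation), among them Aen (2.01 ± 0.14) and Eda2r (3.54 ± 0.42). This call was lost without P21, without P23 and without both (adjusted p = 0.112 without both).

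Lists of 4 secretory or rare cell types were called lower by camera at the preset correlation but not with an estimated one. By fry all 4 were also lower (adjusted p = 1.3e-06 for enteroendocrine, 1.2e-06 for tuft, 0.00287 for Paneth and 0.00411 for goblet cell genes). Enteroendocrine genes fell in 11 of 19 cases (13 adjusted over the list alone; adjusted p = 3.3e-05; adjusted p = 0.132 with an estimated correlation), with the granin Chgb falling by 6.09 ± 0.23. Tuft cell genes had 11 falls and 1 rise among 14 (12 and 1 adjusted over the list alone; adjusted p = 0.00397; adjusted p = 0.0683 with an estimated correlation), the rise being Avil (1.15 ± 0.25). Paneth cell genes had 7 falls and 1 rise among 12 (8 and 1 adjusted over the list alone; adjusted p = 0.0136; adjusted p = 0.432 with an estimated correlation), the rise being Habp2 (2.12 ± 0.34). Goblet cell genes had 7 falls among 16 (10 adjusted over the list alone; adjusted p = 0.0197; adjusted p = 0.376 with an estimated correlation). The adenoma animals lay far apart in both. Paneth cell genes averaged 7.56 and 7.92 in P21 and P23 but 4.47 and 4.44 in P34 and P36, against 8.94 in wild-type monoculture. Goblet cell genes averaged 8.19, 8.50, 5.62 and 6.30 in the same order, against 9.30. Most of both falls thus lay in P34 and P36. Muc2, the gel-forming mucin of goblet cells, fell by 5.45 ± 1.30 on average. Adenoma and wild-type samples came from different animals, so genotype, tissue state and animal cannot be separated, and the culture of the adenoma cells is not given in the sources used here.

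**Figure D2:**
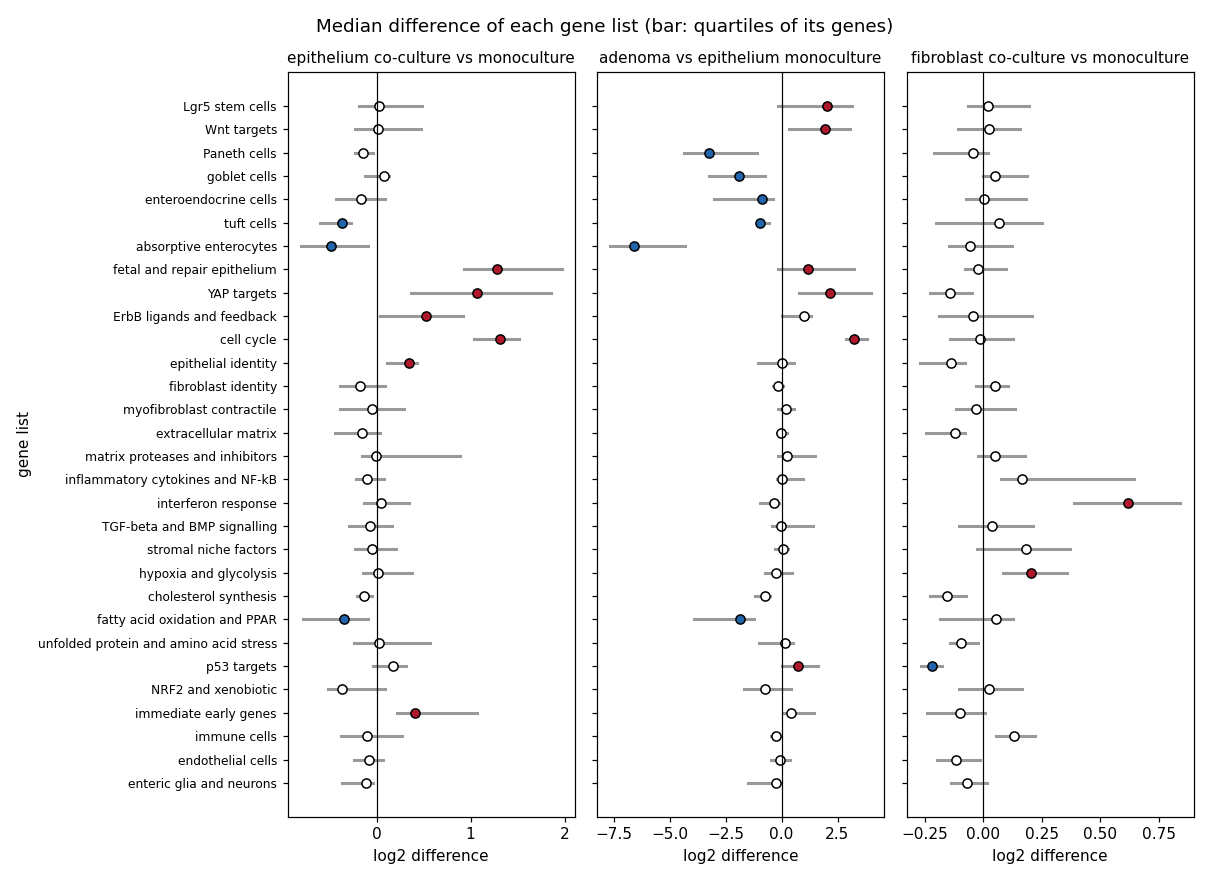
Median log2 difference (horizontal axis, a different range in each panel) of the genes of 30 lists in 3 comparisons. Bars span the quartiles of a list's genes, and filled points are lists called by camera at the preset correlation, red for higher and blue for lower. 9 lists were called in co-cultured epithelium, 12 in adenoma and 3 in co-cultured fibroblasts.

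Against co-cultured epithelium, adenoma had 3439 genes higher and 2583 lower, which turned round after cyclic loess, with 2758 higher and 3055 lower. The largest falls were again in the absorptive cell, with Sis at -9.52 ± 0.21, Fabp1 at -8.07 ± 0.20, Apoa4 at -8.30 ± 0.22 and all 22 absorptive genes falling (22 adjusted over the list alone; adjusted p = 2.6e-25; adjusted p = 2.0e-04 with an estimated correlation). Gabrp (6.83 ± 0.38), Msn (6.45 ± 0.24), Fn1 (6.35 ± 0.42), Cyp1b1 (5.93 ± 0.41) and Myof (5.60 ± 0.32) led the rises, followed by Enah (5.58 ± 0.29), a regulator of actin, the receptor Adgrg6 (5.49 ± 0.41) and the gap junction protein Gja1 (4.98 ± 0.59). Plekhs1, Eya2, Cybrd1 and Cibar1 completed the 12 largest rises, at 4.84 to 5.17, and Clca4b, Rbp2, 2010106E10Rik, Enpep, Cyp2c29, Clec2h, Chp2, Fabp2 and Btnl1 the 12 largest falls, at -8.43 to -7.34. Differences of Sis, Fabp1, 2010106E10Rik, Cyp2c29, Btnl1, Chp2, Gabrp and Gja1 are lower bounds, since 1 of their means lay under the dim level of 2.67. Apc (0.17 ± 0.27), Epcam (-0.75 ± 0.37), Vim (-0.03 ± 0.17) and Col1a1 (0.05 ± 0.17) did not pass. Lgr5 (0.74 ± 0.25) and Acta2 (1.33 ± 0.35) passed, but the calls were lost in 9 and 4 of 18 alternatives, and the probe sets of Lgr5 disagreed. Fatty acid oxidation genes fell in 16 of 18 cases (16 adjusted over the list alone; adjusted p = 6.2e-10; adjusted p = 0.0125 with an estimated correlation). Cell cycle genes rose in 21 of 24 cases (22 adjusted over the list alone; adjusted p = 2.3e-07; adjusted p = 0.521 with an estimated correlation) and Wnt targets in 15 of 23, with 2 falls (15 and 2 adjusted over the list alone; adjusted p = 9.1e-04; adjusted p = 0.429 with an estimated correlation). Fetal and repair genes were not called by camera (median 0.36, adjusted p = 0.294), with 5 rises and 1 fall among 13. By fry, which does not compare them with other genes, they were higher (adjusted p = 0.00367). In all 12 lists were called, 5 higher and 7 lower, and without P21 and P23 2 higher and 6 lower. Without the co-culture sample of animal P28, 3864 genes passed.

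A final comparison asked whether genes that moved with co-culture also differed in adenoma. Of the 490 genes that rose in co-cultured epithelium 435 were higher in adenoma than in monoculture and 14 were lower. Of the 239 that fell, 218 were lower in adenoma and 3 were higher. Sharing the monoculture samples can by itself raise these overlaps, for which no unchanged reference was simulated. With a different monoculture sample for each difference, added after the data were seen, 246 of 280 genes that rose with co-culture were higher in adenoma and 11 lower, and 80 of 109 that fell were lower. With the samples exchanged, the counts were 122 of 140 higher and 8 lower, and 49 of 62 lower. Ccnd1 was 3.27 higher in co-culture and 4.78 higher in adenoma, and Msln 2.86 and 3.82. Nid1 went apart, at 3.37 in co-culture but lower in adenoma, and its 2nd probe set lay at 3.07 and -0.93. The median of the 490 genes was 1.14 in co-culture and 1.83 in adenoma. Across genes, which are not independent replicates, the covariance of the differences was 0.359, against 0.0587 (0.0534 to 0.0654) in 100 simulations of unchanged groups measured against the same monoculture samples. The correlation was 0.602 against 0.576 (0.541 to 0.601) in the simulations. No gene changed in these, so sharing alone sets their correlation, whereas 41.0% of genes differed in adenoma. The simulated correlation is therefore no reference for the real one, and nothing is concluded from their closeness. Both differences share the 2 monoculture samples, which are too few to split with 2 in each part. The simulated covariance is what this sharing gives to unchanged groups with noise independent between genes. Genes that move together would widen its range, so the real value is not judged by that range. With separate monoculture animals for each difference no sample is shared, and the covariance was still 0.330. This argues against sharing as the source of most of the covariance, though each difference then rests on a single monoculture sample.

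**Figure D3:**
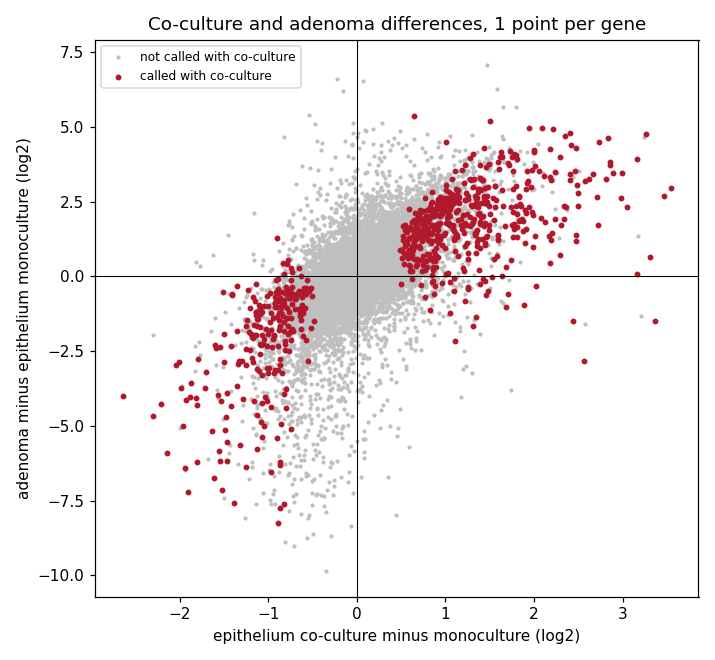
Log2 difference of adenoma (vertical axis) against that of co-cultured epithelium (horizontal axis), both relative to epithelial monoculture, 1 point per gene for 18095 genes. Red points are the 729 genes called with co-culture, most of which lie in the lower left (218 fell in both) and upper right (435 rose in both).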

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

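The tests of fibroblast RNA by the 100 transcripts, of array scaling and of array exchange were chosen after the results were seen, and the other tests of this part before. The co-culture response differed between epithelium and fibroblasts for 200 genes by the interaction test. Besides the 12 genes given in the report (Krt80 3.64, Nid1 3.52, Anxa8 3.30, Ccnd1 3.24, Krt4 3.18, Pbp2 3.05, Cyp2c38 -2.80, Cyp1a1 -2.52, Ugt2b36 -2.34, Cyp2j9 -2.26, Slc5a11 -2.19 and Ces3a -2.11), 15 other genes considered for naming in epithelium passed it. These were Msln (2.91), Plat (2.83), Ajuba (2.79), Anxa3 (2.48), Amotl1 (2.47), Il33 (2.31), Cdk6 (2.29), Ptpn14 (2.27), Anxa1 (1.99), Plaur (1.97), Hk2 (1.74), Prom1 (1.52) and Timp2 (1.47) on the higher side and Cyp2d13 (-2.03) and Slc9a3 (-1.98) on the lower. None of these genes passed in fibroblasts alone, and genes that fibroblasts hardly express could not fall there.

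RNA of fibroblasts in the epithelial samples is argued against as the source of the epithelial response. The 100 transcripts most enriched in fibroblasts (by a median of 7.45) had a median difference of -0.0896 in co-cultured epithelium (quartiles -0.25 and 0.25). Of the 490 genes that rose 99 had a lower mean in fibroblasts than in monocultured epithelium, where mixing could not raise them, but the bound set beforehand was over 100, and 298 of the 490 had a higher mean in fibroblasts than in co-cultured epithelium, so this count decided nothing. Scaling stays open: cyclic loess between the 4 arrays called 716 of the 729 genes again, but it moved a difference by a median of only 0.00473 and so tested nothing. A difference between monoculture and co-culture plates other than the fibroblasts, such as medium carried over with the insert, was not tested and stays open beside a response to soluble factors.

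An adenoma animal stood apart from the other 3 for 5 of 151 genes considered for naming. The 5 in 100 that chance gives assumes independent animals, and these lay in close pairs, so the count is not judged against it. The gap as a share of the range was 0.950 for Arg2 (P23 highest, 3.53), 0.890 for Rrm2 (P23 highest, 9.72), 0.882 for Ccne1 (P21 lowest, 7.48), 0.871 for Anxa1 (P34 highest, 11.92) and 0.849 for Anxa8 (P21 lowest, 8.58).

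In co-cultured fibroblasts 1 gene was called, and 5 of the 10 splits of the 6 samples into groups of 3 gave as many, the highest other split giving 203. For gene lists 6 of the 10 splits gave at least the 3 called, the highest other giving 11. With 10 splits a share under 0.05 cannot be reached. The split with 203 genes set both cultures of Pl_I and the co-culture of Pl_II against both cultures of Pl_III and the monoculture of Pl_II, so it parts Pl_I from Pl_III. The split with the cultures of Pl_II exchanged parts these animals alike but gave 2 genes, so the reason for the 203 stays open. Among the 4 splits that part all 3 animals, the other 3 gave 0 genes each and 1, 2 and 2 lists.

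An exchange of arrays between animals of this series cannot account for the sex transcripts that went against the male label. All 16 arrays are labelled male, so any such exchange would leave as many arrays against their label. In 5 of 5 animals the monoculture and co-culture arrays carried the same sex transcripts. These are the values that showed the pattern, so the count tests nothing about the label, and it could not reveal an exchange of both arrays of an animal. The count of 5 also rests on following the title of the third fibroblast monoculture array, whose other label names a different animal. A wrong sex label for animals P28 and Pl_III stays open, and no biological explanation was tested.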

How the results depend on the processing

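The alternatives that left out whole animals were chosen after seeing the data, all others before. No named gene that had passed changed direction, but cyclic loess turned the balance of higher and lower genes in both adenoma comparisons. Leaving out 1 epithelial sample leaves a lone sample, assumed to vary like the other groups. In co-cultured epithelium the 729 genes became 0 in a fit of the compared groups only, 1922 with the animal as a replicate block, 68 without animals P28 and Pl_III, 408 with a 2-fold minimum, 1196 at an adjusted p under 0.1 and 202 to 389 without single samples. Its 9 lists became 1 with an estimated correlation. In fibroblasts the single gene was lost (0 genes) in a fit of the compared groups only, with the block, with the trended robust prior, without P28 and Pl_III, without Pl_I and in 5 of 6 fits without single samples (0 to 1). Its 3 lists became 8 with the block, 6 without P28 and Pl_III, 0 with an estimated correlation, 0 with fry and 1 to 10 without single samples. Adenoma against monoculture gave 4155 genes with a 2-fold minimum and 2 lists with an estimated correlation. Adenoma against co-culture gave 3984 genes without P28 and Pl_III, 2974 with a 2-fold minimum, 3864 to 5814 without single samples, and 2 lists with an estimated correlation. The interaction gave 862 genes with the block, 5 without P28 and Pl_III, 448 at an adjusted p under 0.1 and 56 to 164 without single samples. The covariance was 0.299 with no filter and 0.330 to 0.448 without single samples, judged against the SD of the latter. For 219 combinations of gene and comparison considered for naming, more than the report gives, 3157 of 3470 values kept direction and side of the threshold, 269 kept direction without passing, 11 passed newly and 33 changed sign in genes that had not passed.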

Other observations

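The gene families and single genes of this part, and the alternatives without whole animals, were chosen after the results were seen. The test of intestinal genes on 3 arrays was also chosen after, and the other tests of the stomach pattern after that pattern but before the values of their genes were seen. Some members of families of detoxifying enzymes fell in co-cultured epithelium. Of 79 cytochrome P450 genes 9 fell and 1 rose, of 18 carboxylesterases 5 fell and 0 rose, and of 7 glucuronosyltransferases 3 fell and 0 rose, with family medians of -0.40, -0.86 and -1.16. Annexins rose in 4 of 11 cases and S100a genes in 4 of 16, with 0 falling in either. In adenoma 40 of the 79 cytochrome P450 genes fell and 4 rose, and 12 of 18 carboxylesterases and 6 of 7 glucuronosyltransferases fell. After cyclic loess 9, 5 and 3 members of the 3 enzyme families fell in co-culture and 39, 12 and 6 in adenoma, and 5 annexins and 4 S100a genes rose in co-culture. No enrichment test was made for families picked in this way.

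Adenoma animals P34 and P36 carried some transcripts of stomach epithelium: of 13 stomach genes not seen before, 6 lay more than 1 above monoculture in P34 and 8 in P36, but also 5 in P21 and P23. Nkx6-3, a transcription factor of the gastric antrum, lay at 8.55 in P34 and 8.87 in P36, against 3.30 in P21, 3.53 in P23 and 3.77 in wild-type monoculture. The intestinal genes Muc13 (3.26 and 2.85), Gucy2c (2.60 and 3.13) and Isx (2.96 and 2.65) lay near their fibroblast level in P34 and P36, where P21 and P23 had Muc13 at 10.80 and 10.92 and Gucy2c at 9.63 and 9.44. These 4 genes had led to the pattern, in a ranking of differences between the adenoma animals, so they describe it and test nothing. Among the 13, Tff2 lay at 5.92 and 7.30 in P34 and P36 against 3.72 and 4.04 in P21 and P23, Vsig1 at 11.05 and 11.47 against 9.25 and 8.98, the parietal cell genes Atp4a and Atp4b at 3.00 to 3.27, and Capn9 lower, at 4.00 and 4.10 against 5.37 and 6.17.

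A list of 14 stomach and 13 intestinal genes was written for the tests, and 5 of them (Nkx6-3, Cdh17, Gucy2c, Muc13 and Isx), first taken as unseen in error, were removed because that ranking had shown them. A fault of a single array is argued against for those intestinal transcripts that were lower, since the median of the 9 other intestinal genes lay below that of every array of P21 and P23 in 3 of 3 arrays of P34 and P36 (-4.75, -4.58 and -4.63 from monoculture, against -1.88, -2.29 and -1.89). The loss was not shared by all 9. Heph (4.49 and 4.56 against 7.92 and 8.12) and Cdhr5 (6.86 and 5.84 against 8.86 and 9.17) were lower in P34 and P36. Lgals4 and Gpa33 hardly differed, and Hnf4g, whose value is the median of P36, was not lower there than in P21 and P23. For the stomach transcripts the bound set decided nothing: over the other 13 stomach genes the arrays of P34 differed from monoculture by medians of 0.983 and 0.770 (1.09 and 0.937 with Nkx6-3), between the 0.5 of a fault and the 1 that would exclude it. Stomach tissue in place of intestinal tissue cannot be told apart either: of these 9 genes, among them Cdx2 at 7.04 and 6.67, 6 lay more than 2 above the fibroblast mean in every array of P34 and P36 (7 of all 13). This met the bound of 0.5 of the genes set beforehand, though not with a margin of 1 binomial SD added after the values were seen, and only 1 or 2 lay within 1 of the fibroblast mean, both against stomach tissue. It was not taken as excluding it, since no stomach sample was arrayed to show which of these genes stomach makes, and since the removal of Cdh17, Gucy2c, Muc13 and Isx took out genes that were lower in these animals. That these adenomas may hold a gastric programme is a hypothesis, and the site each was taken from is not given in the sources used here. The titles of P21 and P23 carry T2 and those of P34 and P36 do not, a split along the same animals whose meaning is not given.

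Without P34 and P36 7073 genes changed between adenoma and monoculture, and without P21 and P23 6929.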
